A study of Mus musculus with 4 samples.

How the data were processed

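Liver RNA of 4 IlrunKO and 4 WT mice was hybridised in pairs to 4 two-colour arrays (design Agilent-026655, 44397 spots), 500 ng of RNA per sample being labelled, per the labels. Genotype and dye of each channel were taken from the labels, which put IlrunKO in Cy5 on 2 arrays and in Cy3 on the other 2. Pooling of mice is not stated, and an individual mouse per channel is assumed. The authors deposited scanner files holding raw intensity (mean pixel brightness of each spot and median of its local background), processed intensity (background-subtracted and dye-normalised) and a log10 ratio of Cy5 over Cy3, made with Agilent Feature Extraction 10.10.1.1 per the file headers. They also deposited a table of values, which holds log2 ratios of IlrunKO over WT on every array, as checked against the scanner ratio (across spots, r = 0.987, 0.982, -0.983 and -0.981 on arrays 1 to 4) and against the Ilrun probe. Limma is the tool named in the submitters' processing notes for that table; its version, background correction and normalisation are not given in the sources used here.

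The ratios reported here were recomputed from raw intensity with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8) to read files. Each channel was background-corrected with normexp (offset 50), and log2 ratios were normalised by loess within each array, with 1377 control spots at weight 0. Spots that Feature Extraction marked as outliers were left out (381, 280, 239 and 224 on arrays 1 to 4); no spot was saturated. Spots of the same probe were averaged, giving 39429 probes. Of these, 26055 were named by RefSeq accession and 4125 by symbol or synonym against the mouse RefSeq annotation, and 9249 kept the name in the files. The brightest probe stood for each gene, chosen without regard to genotype. A gene was kept where its probe was well above background in at least 3 of the 4 IlrunKO or 3 of the 4 WT channels, which left 19675 of 31709 genes. Probe positions are those in the files (mm9); exons and introns were not assigned, since the annotation at hand is of another build.

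Each gene was fitted by limma (lmFit and eBayes) with a dye term and a genotype term, and p was adjusted by Benjamini-Hochberg over the genes kept, two-sided, with a threshold of 0.05. The fit left 2 residual degrees of freedom and a prior of 2.83, and its median standard error was 0.0567. The dye term also takes up any difference in the ratio of IlrunKO over WT between arrays 1 and 2 and arrays 3 and 4, so only the spread within each orientation enters the error. Gene lists were tested with camera on the moderated statistics (inter-gene correlation preset at 0.01), with an estimated correlation and by fry beside it, over 45 lists with at least 5 tested members, adjusted together. Lists cover lipid, glucose, drug, stress, immune and growth pathways and the cell types that a liver sample could hold. Shares of genes near Ilrun were compared by Fisher's exact test, two-sided.

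Named genes followed a rule: Ilrun with every probe; the 12 largest rises and the 12 largest falls among genes with a single gene symbol that passed with the same sign on all 4 arrays; and for each list that passed or had at least 2 members passing, up to 4 members with the smallest p, those that passed first. PPARalpha and both lipoprotein lists were given this whether they passed or not, and genes next to Ilrun or known to differ between substrains were to be named if they passed. If fewer than 5 genes had passed in a direction, the 5 with the smallest p there were to be named as not passing. Fold and level differences of other probes of a named gene were stated where their call or direction differed. The grouping, model, filter, threshold, lists, naming rule and all alternatives but 1 were fixed before the data were examined.

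Tested on simulated data with the same design (19566 genes, 5 runs, 200 changed genes each), the fit recovered 51.6% of changes of 0.5 on the log2 scale and 93.6% of changes of 1, and 43 of 903 calls were false (4.76%). A list of 30 genes shifted by 0.2 was called in 5 of 5 runs, and 0 of 220 unshifted lists were called. Variances and errors were drawn from the fitted model itself, so a false share near the threshold follows from that setting. It does not measure the share of false calls in the real data. Independent genes were simulated, so the list test was not tried on correlated genes.

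Alternatives changed 1 step at a time, except that a trended and a robust variance were set together and that the processed intensity and the deposited values replace background correction and normalisation together. They covered the dye term, background correction, normalisation, the filter, the probe per gene, the variance model, array weights, separate-channel models, the deposited values, leaving out each array, the threshold, and the window around Ilrun. Fits without an array kept the dye term, so the array left alone in its orientation weighed as much as the other pair together. Their values are therefore not plain means of the remaining arrays. A call both with and without the dye term was added after the data were seen. The deposited values and the processed intensity were used only as alternatives, and the log10 ratio only to check direction and scale. Control spots and the scanner's other quality columns were left out, as they measure no gene.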

Results

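Liver RNA of 4 male IlrunKO mice and 4 male wild-type (WT) mice was compared on 4 two-colour Agilent arrays, each holding 1 IlrunKO and 1 WT sample labelled with different dyes. IlrunKO mice lack Ilrun, a regulator of inflammation and lipids, in the whole body. All mice were C57BL/6, ate chow and were fasted for 4 h before the liver was taken. IlrunKO RNA carried the red dye Cy5 on arrays 1 and 2 and the green dye Cy3 on arrays 3 and 4. Between 60.0% and 67.3% of the 39429 probes were well above background in each of the 8 channels. The number of arrays limits the precision: the median 95% confidence interval of a log2 ratio reached 0.147 to either side. All arrays shared 1 slide and 1 scan, so no slide or scan batch separated the genotypes. Values below are log2 ratios of IlrunKO over WT with their SD over the 4 arrays (n = 4), and a gene is said to rise or fall where limma gave it an adjusted p under 0.05.

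The first comparison asked how far the Ilrun transcript was lost. The brighter Ilrun probe (named D17Wsu92e in the files) was 18.5-fold lower in IlrunKO liver, with a log2 ratio of -4.21 ± 0.24 (SD, n = 4) and values of -4.12, -4.11, -4.04 and -4.56 on the 4 arrays. It lies on chromosome 17 at 27888506 to 27888565 of mouse genome mm9, and fell with an adjusted p of 0.00335, below that of any other gene tested. A dimmer Ilrun probe at 27930857 to 27930916 was at least 4.42-fold lower, with a log2 ratio of -2.15 ± 0.34 (SD, n = 4) and an adjusted p of 0.0264 over all probes. IlrunKO signal stayed well above background on 4 of 4 arrays at the brighter probe and on 1 of 4 at the dimmer one. Which part of Ilrun was deleted is not given in the sources used here, so residual signal at either probe cannot be set against the deletion.

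The second comparison asked which other liver transcripts differ in mice without Ilrun. Cfd, which encodes complement factor D (adipsin), had the largest rise: it was 14.2-fold higher, with a log2 ratio of 3.82 ± 1.22 (SD, n = 4). The sulfotransferase gene Sult2a7 (Gm7231 in the files) rose 6.07-fold, and the long noncoding RNAs Meg3 and Neat1 rose 4.75-fold and 4.68-fold, with log2 ratios of 2.60 ± 0.42, 2.25 ± 0.74 and 2.23 ± 0.38. The largest falls of genes with a symbol after Ilrun were those of Fabp5l2 and Fabp5, by log2 ratios of -1.73 ± 0.56 and -1.66 ± 0.39. Fabp5 encodes a carrier of fatty acids inside cells, and Fabp5l2 has a near-identical sequence, so the probes of Fabp5 and Fabp5l2 may not tell the pair apart. G6pc, the catalytic subunit of glucose-6-phosphatase, was 2.15-fold lower (-1.10 ± 0.55) and Ppp1r3g, which directs a phosphatase to glycogen, was 2.05-fold lower (-1.03 ± 0.58), and neither passed without the dye term.

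Of 19675 genes tested, 270 changed (1.37%), 141 upward and 129 downward, and 268 of them had the same sign on all 4 arrays. At least 2-fold changes were seen in 38 genes, 22 upward and 16 downward. Among genes with a symbol, the 12 largest rises also held 4930579F01Rik (2.03 ± 0.62), the urinary pheromone carrier Mup20 (1.68 ± 1.22), Zfr2 (1.42 ± 0.06), the carboxylesterase gene Ces4a (1.30 ± 0.23), Kbtbd11 (1.30 ± 0.36), Bhmt (1.21 ± 1.00), Ankrd2 (1.12 ± 0.38) and Adrb3 (1.04 ± 0.34). Bhmt encodes the enzyme that turns homocysteine into methionine with betaine, and Adrb3 the beta-adrenergic receptor best known from fat cells. Among genes with a symbol, the 12 largest falls after Ilrun also held Lrtm1 (-1.59 ± 0.41), the adhesion receptor gene Adgrv1 (-1.24 ± 0.44), the oxysterol hydroxylase gene Cyp39a1 (-1.16 ± 0.87), the stress cytokine gene Gdf15 (-1.12 ± 0.66), Atg16l2 (-1.07 ± 0.32), the kynurenine aminotransferase gene Kyat3 (-1.06 ± 0.28), the mitochondrial carrier gene Slc25a25 (-1.05 ± 0.25) and the cytokine receptor gene Lifr (-1.02 ± 0.34). Adjusted p ran from 0.00984 for Zfr2 to 0.0496 for Ankrd2 among these rises, and from 0.0253 for Ppp1r3g to 0.0461 for Atg16l2 among these falls. All 24 genes had the same sign on 4 of 4 arrays, as the naming rule required. Transcripts without a gene symbol were not ranked with them, although 8 rose by more than Adrb3 and 1 fell by more than Lifr. Without adjustment, 4034 of all 19675 genes had a limma p under 0.05. Counts of list members with an unadjusted p under 0.05, given below, are to be read against that share.

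Probes of the same gene differed for some of these. Kbtbd11 had other probes at 0.07 and -0.02 (adjusted p = 0.45 and 0.891), and Lifr had others at 0.14 and 0.08 (adjusted p = 0.68 and 0.84), so Kbtbd11 and Lifr rest on 1 probe each. Meg3 had others at 0.43 (adjusted p = 0.0839) and 1.24 (adjusted p = 0.0485), and Mup20 had another at 0.83 (adjusted p = 0.0586). Mup20 ratios were 2.53 and 2.88 on the arrays with IlrunKO in Cy5 but 0.29 and 1.04 on those with IlrunKO in Cy3. Bhmt ratios were likewise 2.07 and 2.03 against 0.65 and 0.08, those of Cyp39a1 -1.87 and -1.94 against -0.52 and -0.30, and those of Ppp1r3g -1.55 and -1.53 against -0.53 and -0.52. Without the dye term in the model 181 genes passed, 157 of them among the 270. Of the 24 named genes, 18 passed there, while Mup20, Bhmt, Cyp39a1, Gdf15, G6pc and Ppp1r3g did not. Without array 3 or without array 4, Ilrun was the only gene that passed, and the residual spread there came from arrays 1 and 2 alone. Without array 1, 464 genes passed (64.2% of them higher), 186 of them among the 270, and without array 2, 256 genes passed, 134 of them among the 270. Cfd lost its call in 8 of 19 alternatives, the most of the named genes that passed. It stood at 3.42 without array 1, 3.19 without array 3 and 4.45 without array 4, and also did not pass with Agilent processed signals, with median centring, without the filter, with the mean of a gene's probes, or with a trended robust variance.

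**Figure D1:**
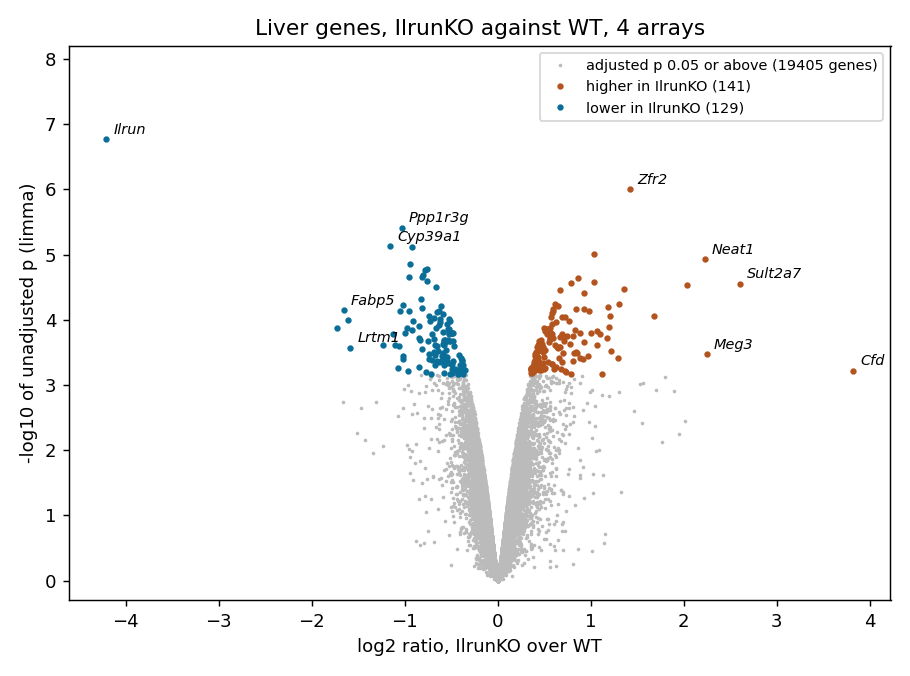
The log2 ratio of IlrunKO over WT is plotted against -log10 of the unadjusted limma p for 19675 liver genes, with the 141 rises in orange and the 129 falls in blue. Ilrun lies apart at -4.21 and Cfd at 3.82.

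**Figure D2:**
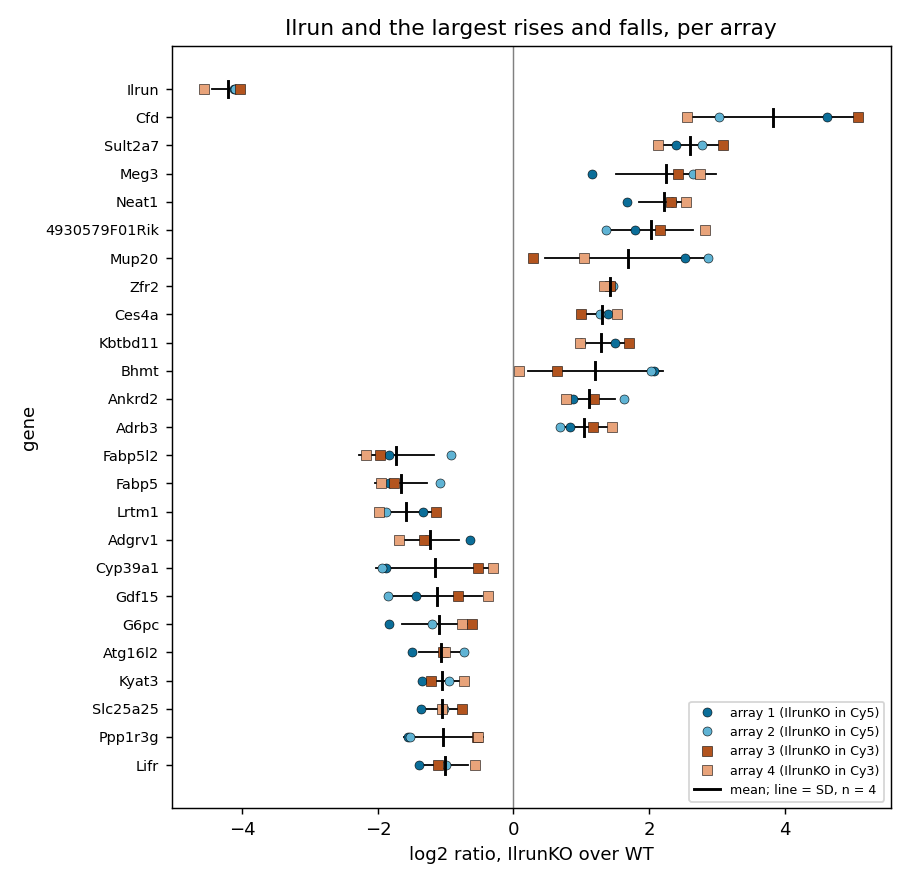
Log2 ratios of Ilrun, the 12 largest rises and the 12 largest falls of genes with a symbol are plotted for each of the 4 arrays, with a bar for the mean and a line for 1 SD to either side. Mup20, Bhmt, Cyp39a1 and Ppp1r3g are among the genes that sit apart by dye orientation, circles for IlrunKO in Cy5 and squares for IlrunKO in Cy3, while Zfr2 has an SD of 0.06.

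Genes of fatty acid and triglyceride synthesis were lower as a group in IlrunKO liver, with 21 of 29 members below 0 and a list mean of -0.310 ± 0.128 (SD over 4 arrays). Fasn, the fatty acid synthase, fell 1.58-fold (-0.66 ± 0.38, adjusted p = 0.0347) and the desaturase gene Fads1 fell 1.80-fold (-0.84 ± 0.44, adjusted p = 0.0461). The desaturase gene Fads2 stood at -0.55 (adjusted p = 0.0546), with another probe at -0.63 (adjusted p = 0.034), and the pyruvate kinase gene Pklr stood at -0.39 (adjusted p = 0.0707). Over all genes, 2 members fell and 27 did not pass. Adjusted over the list alone, 2 rose and 15 fell. The list passed camera with the preset correlation (adjusted p = 0.00108), and lost that call at an adjusted p = 0.939 with an estimated correlation. Fasn and Fads1 did not pass without the dye term.

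PPARalpha targets, which serve fatty acid oxidation and fasting, were split: 36 of 58 members lay above 0 and 22 below, with a list mean of 0.0784 ± 0.215 (SD over 4 arrays). The liver hormone gene Fgf21 fell (adjusted p = 0.0433), and since its IlrunKO signal was not well above background on any array, it was at least 1.67-fold lower. Fgf21 stood at -0.69 without array 1 and -0.79 without array 2, and passed in neither. The lipid droplet gene Cidec stood at 1.53 ± 0.58 (adjusted p = 0.0547), with another probe at 0.71 (adjusted p = 0.0413), and the lipoprotein lipase gene Lpl at -0.34 ± 0.63 (adjusted p = 0.0681), above 0 on arrays 1 and 2 (0.27 and 0.14) but below 0 on arrays 3 and 4 (-0.81 and -0.95). Over all genes 1 member passed, and adjusted over the list alone 3 rose and 3 fell. The list did not pass (adjusted p = 0.441). Without array 1 its mean was -0.0513, and without array 2 it was 0.208 and passed.

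Among 21 genes of lipoprotein assembly, Apoc2, a cofactor of lipoprotein lipase, rose 1.65-fold (0.72 ± 0.25, adjusted p = 0.0474), although array 1 stood apart at 1.09. Apom stood at -0.71 (adjusted p = 0.0588), Apoa5 at 0.39 (adjusted p = 0.0857) and Apoa1 at -0.37 (adjusted p = 0.0943). That list had a mean of -0.103 ± 0.159 (SD over 4 arrays) and did not pass (adjusted p = 0.204). With median centring it was -0.257 and passed. Its mean was 0.0116 and 0.0535 on arrays 1 and 2 but -0.221 and -0.258 on arrays 3 and 4. Of its members, 1 rose over all genes, while 4 rose and 5 fell adjusted over the list alone. Among 23 genes of lipoprotein uptake and plasma lipid handling, no member passed over all genes in limma (10 had an unadjusted p under 0.05), and 2 rose and 1 fell adjusted over the list alone. Angptl8 (Gm6484 in the files), an inhibitor of lipoprotein lipase, stood at 0.56 (adjusted p = 0.0515), Lpl at -0.34, the cholesterol exporter gene Abcg1 at 0.36 (adjusted p = 0.0945) and Mylip at -0.25 (adjusted p = 0.15). The list mean was 0.00571 ± 0.0842 (SD over 4 arrays, adjusted p = 0.912), and its median and test had the opposite sign.

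Of 20 genes of gluconeogenesis and the fasting response, G6pc and Fgf21 fell, Trib3 stood at 0.88 (adjusted p = 0.0547) and the insulin-repressed gene Igfbp1 at -1.42 (adjusted p = 0.109). The list mean was -0.221 ± 0.243 (SD over 4 arrays) and did not pass (adjusted p = 0.0758). Over all genes 2 members passed, and adjusted over the list alone 1 rose and 3 fell.

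**Figure D3:**
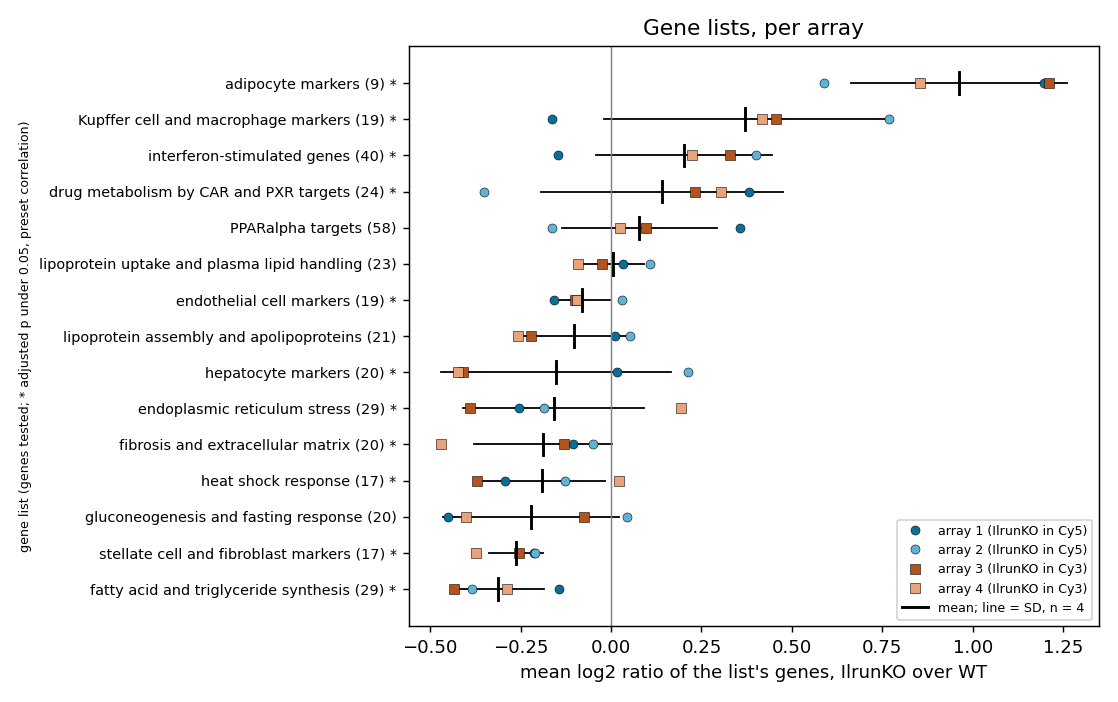
The mean log2 ratio of each list's tested genes, IlrunKO over WT, is plotted for each of the 4 arrays, with a bar for the mean over arrays and a line for 1 SD to either side. Adipocyte markers were highest at 0.962 and fatty acid and triglyceride synthesis lowest at -0.310; asterisks mark an adjusted p under 0.05 with the preset correlation.

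Markers of other cell types were measured beside the hepatocyte genes. Adipocyte markers were higher in IlrunKO liver (list mean 0.962 ± 0.299, SD over 4 arrays): Cfd and Adrb3 rose, Cidec stood at 1.53 and the adipogenic receptor gene Pparg at 0.69 (adjusted p = 0.0994), while the abundant fat cell gene Fabp4 stood at -0.11 (adjusted p = 0.327). Of the 9 members tested, 2 rose over all genes and 8 adjusted over the list alone. The 9 were above background in at least 3 of 4 IlrunKO or 3 of 4 WT channels, Retn through the IlrunKO channels only. The adipocyte list passed with the preset correlation (adjusted p = 6.06e-05), and lost that call at an adjusted p = 0.939 with an estimated correlation. Kupffer cell and macrophage markers were higher, with 18 of 19 members above 0 and a list mean of 0.370 ± 0.389 (SD over 4 arrays). Cd68 stood at 0.21, Fcer1g at 0.54, Ctss at 0.55 ± 0.48 and the scavenger receptor gene Cd163 at -0.25, with adjusted p from 0.116 for Cd68 to 0.214 for Ctss. No Kupffer marker passed in limma over all genes or adjusted over the list alone (9 had an unadjusted p under 0.05), and the list passed with the preset correlation (adjusted p = 0.000523), and lost that call at an adjusted p = 0.939 with an estimated correlation. Array 1 went the other way for Kupffer markers (-0.164), so the mean was 0.603 without array 1 and 0.137 without array 2, and the list passed in both.

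Stellate cell and fibroblast markers were lower: all 17 members lay below 0, with a list mean of -0.263 ± 0.0755 (SD over 4 arrays). The collectin gene Colec11 stood at -0.34 (adjusted p = 0.0528), Ecm1 at -0.35, Hand2 at -0.31 and the retinol esterifying enzyme gene Lrat at -0.49. No member fell over all genes in limma (12 had an unadjusted p under 0.05), and 8 fell adjusted over the list alone. Genes of fibrosis and extracellular matrix were also lower (-0.189 ± 0.191, SD over 4 arrays; 17 of 20 below 0), with Sparc at -0.36, Pdgfrb at -0.27, Acta2 at -0.22 ± 0.35 and Col4a2 at 0.28, and no member passed over all genes or adjusted over the list alone (8 had an unadjusted p under 0.05). The fibrosis list shared 6 members with the stellate list, the 14 others had a mean of -0.122, and without array 4 the list mean was -0.104. Both lists passed with the preset correlation (adjusted p = 1.46e-06 for stellate markers and 0.00181 for fibrosis), and both lost that call at an adjusted p = 0.939 with an estimated correlation. Before adjustment, camera with an estimated correlation gave p = 0.0454 for stellate markers and 0.239 for fibrosis.

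Endothelial cell markers had a list mean of -0.0809 ± 0.0788 (SD over 4 arrays; 16 of 19 below 0), with Oit3 at -0.26, Bmp2 at -0.31, Stab1 at -0.16 and Gpr182 at -0.16 ± 0.64. Gpr182 lay below 0 on arrays 1 and 2 (-0.74 and -0.68) but above 0 on arrays 3 and 4 (0.49 and 0.28). Hepatocyte markers had a list mean of -0.151 ± 0.317 (SD over 4 arrays; 18 of 20 below 0), with the transferrin gene Trf at -0.62 ± 0.82, the albumin gene Alb at -0.36 ± 0.86, Apoa1 at -0.37 and Asgr1 at 0.16. The hepatocyte list mean was 0.0172 and 0.212 on arrays 1 and 2 but -0.411 and -0.424 on arrays 3 and 4. Alb ratios were 0.54 and 0.21 on arrays 1 and 2 but -1.07 and -1.11 on arrays 3 and 4. No member of either list passed over all genes in limma, while 4 endothelial and 9 hepatocyte markers had an unadjusted p under 0.05. The endothelial count was near the share over all genes. Adjusted over the list alone, 2 endothelial and 3 hepatocyte markers fell. With the preset correlation the adjusted p was 0.0326 for endothelial and 0.0054 for hepatocyte markers, both calls lost at an adjusted p = 0.939 with an estimated correlation and both also lost without the dye term. The endothelial list also lost its call without background correction, with a normexp offset of 0, with Agilent processed signals and with the deposited values. The endothelial mean was -0.0342 without array 1, -0.0793 without array 3 and -0.128 without array 2, and the hepatocyte mean was -0.103 without array 1; of these the endothelial list passed only without array 2, and the hepatocyte list did not pass.

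Interferon-stimulated genes were higher as a group, with 36 of 40 members above 0 and a list mean of 0.202 ± 0.243 (SD over 4 arrays). The antiviral gene Oasl1 stood at 0.79 (adjusted p = 0.0603), the interferon-induced GTPase genes Ifi47 and Igtp at 0.71 (adjusted p = 0.0759) and 0.45 (adjusted p = 0.102), and Cmpk2 at 0.16 (adjusted p = 0.166). No member passed over all genes in limma (8 had an unadjusted p under 0.05, near the share over all genes), and 2 rose adjusted over the list alone. The list passed with the preset correlation (adjusted p = 0.000154), and lost that call at an adjusted p = 0.939 with an estimated correlation. Like the Kupffer markers, it was below 0 on array 1 (-0.146); its mean was 0.339 without array 1, and 0.0652 and no longer past the threshold without array 2. Acute phase proteins moved by array as well, with list means of -0.686, 1.25, 0.486 and -0.0482 on arrays 1 to 4 and no call (adjusted p = 0.702).

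Genes of endoplasmic reticulum stress were lower as a group, with 23 of 29 members below 0 and a list mean of -0.159 ± 0.250 (SD over 4 arrays). The stress transcription factor gene Atf5 fell 1.80-fold (-0.85 ± 0.16, adjusted p = 0.0347) and the glutathione-degrading enzyme gene Chac1 fell 1.89-fold (-0.92 ± 0.19, adjusted p = 0.0347), while Trib3 stood at 0.88 and Sel1l at -0.52. Over all genes 2 members fell, and adjusted over the list alone 1 rose and 2 fell. Array 4 went the other way, with a list mean of 0.195. Heat shock genes had a list mean of -0.192 ± 0.176 (SD over 4 arrays; 15 of 17 below 0), with the small chaperone gene Hspb1 at -0.93 (adjusted p = 0.0591), Dnajb1 at -0.24, Dnaja1 at -0.33, where another Dnaja1 probe read 0.01, and Fkbp4 at -0.21 ± 0.48. Fkbp4 lay above 0 on arrays 1 and 2 (0.21 and 0.19) but below 0 on arrays 3 and 4 (-0.68 and -0.56). No heat shock member passed over all genes in limma (5 had an unadjusted p under 0.05), and 1 fell adjusted over the list alone. On array 4 the heat shock mean lay above 0 (0.0227). With the preset correlation the adjusted p was 0.00848 for endoplasmic reticulum stress and 0.00822 for heat shock, both calls lost at an adjusted p = 0.939 with an estimated correlation. The endoplasmic reticulum stress list mean was -0.305 without array 4 and -0.0127, no longer past the threshold, without array 3; heat shock was not called without array 1 (-0.150) or array 3 (-0.0934).

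Drug metabolism genes controlled by the receptors CAR and PXR had a list mean of 0.141 ± 0.334 (SD over 4 arrays; 15 of 24 above 0). The cytochrome genes Cyp2b10 and Cyp2b9 stood at 1.80 ± 0.95 (adjusted p = 0.0513) and 1.20 ± 0.57 (adjusted p = 0.064), Cyp2c54 at 0.36 (adjusted p = 0.0702) and the sulfotransferase gene Sult1d1 at 0.40 ± 0.40 (adjusted p = 0.083). No member passed over all genes in limma (13 had an unadjusted p under 0.05), and 10 rose and 2 fell adjusted over the list alone. The list passed with the preset correlation (adjusted p = 0.0268), and lost that call at an adjusted p = 0.939 with an estimated correlation. Array 2 lay at -0.351 and the other arrays from 0.231 to 0.380. The mean was 0.324 without array 2, -0.0420 without array 1 and 0.123 without array 4, with no call in the latter pair. Without array 1, array 2 alone weighed as much as arrays 3 and 4 together, and the sign there rests on that weighting. The list also lost its call with Agilent processed signals (0.206) and turned with median centring (-0.00113).

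Cell cycle genes moved both ways. The ribonucleotide reductase gene Rrm2 fell 1.94-fold (-0.96 ± 0.36, adjusted p = 0.0303) and the mitotic gene Birc5 rose 1.90-fold (0.93 ± 0.17, adjusted p = 0.0347), although another Birc5 probe read 0.16 (adjusted p = 0.16) and Rrm2 did not pass without the dye term. The replication licensing gene Mcm6 stood at 0.57 (adjusted p = 0.0547) and Ccnd1 at -0.53 (adjusted p = 0.0725). The list of 22 genes had a mean of 0.0201 ± 0.0788 (SD over 4 arrays) and did not pass (adjusted p = 0.68), with 1 rise and 1 fall over all genes and 4 rises and 4 falls adjusted over the list alone.

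Of 45 lists tested, 11 passed with the preset correlation, 4 higher and 7 lower, and 34 did not (adjusted p from 0.0758 to 0.961). No list passed with an estimated correlation (1 had an unadjusted p under 0.05), and none passed by fry's directional test, which gave 5 lists an unadjusted p under 0.05. The adjustment gave each of the 11 the same 0.939 with an estimated correlation, so that value does not rank them. Their unadjusted p there ran from 0.0454 for stellate markers to 0.464 for endoplasmic reticulum stress. Each correlation was estimated with 2 residual degrees of freedom. Among the 11 lists the estimates ran from 0.0453 for stellate markers to 0.799 for Kupffer markers, against the preset 0.01. Fry's test for change in either direction passed for 21 lists, 5 of them among the 11: stellate and adipocyte markers, fatty acid and triglyceride synthesis, endoplasmic reticulum stress, and CAR and PXR targets. That test asks whether members change at all, not whether a list differs from other genes. It also passed for ribosomal proteins (adjusted p = 0.0172) and oxidative phosphorylation (adjusted p = 0.0307), so it does not single out those 5 lists. In 5 of the 11 lists the call held in each of the 4 fits that left out 1 array: stellate, adipocyte and Kupffer markers, fatty acid and triglyceride synthesis, and fibrosis. The mean, median and test differed in sign for 10 of the 45 lists, none of them among the 11.

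The next comparison asked whether genes near Ilrun differed more often than others, as flanking sequence carried with a targeted allele could bring about. Within 10 Mb of Ilrun, 9 of 506 genes changed, against 260 of 19026 elsewhere (1.78% and 1.37%; Fisher's exact test, two-sided, p = 0.434). The 9, all named after their values were seen, were Cyp4f14 (-0.82), Ccnf (-0.81), the class I histocompatibility genes H2-Q10 (-0.69) and H2-T3 (-0.59), Metrn (-0.55), Amdhd2 (0.37), Ddx39b (0.43), Abca3 (0.62) and an unnamed transcript (0.70); Amdhd2 and Ddx39b did not pass without the dye term. None of the 20 tested genes lying next to Ilrun passed in limma (4 had an unadjusted p under 0.05, near the share over all genes). Nor did any of the 3 genes known to differ between C57BL/6 substrains (0 had an unadjusted p under 0.05). Without array 1, genes near Ilrun passed more often than others, by 1.63 percentage points (Fisher's exact test, p = 0.025).

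**Figure D4:**
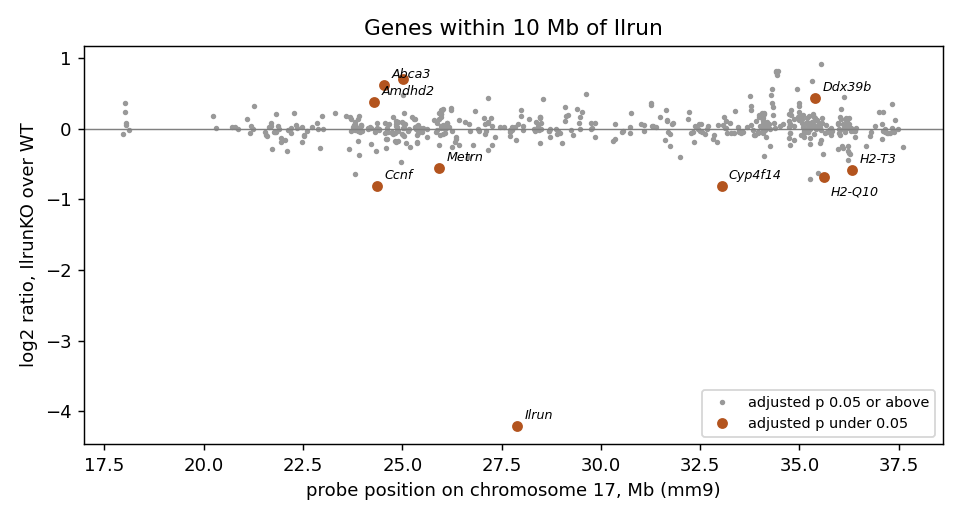
Log2 ratios of IlrunKO over WT are plotted against probe position on chromosome 17 (mm9, Mb) for the genes within 10 Mb of Ilrun, with genes past an adjusted p of 0.05 in orange. Ilrun lies at -4.21 and the 9 other genes that passed lie between -0.82 and 0.70.

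The last comparison measured the dye effect of each probe, Cy5 over Cy3 whatever the genotype. No gene passed for the dye effect in limma, while 3601 had an unadjusted p under 0.05, against 4034 for genotype and 983.75 by chance. Its SD over genes was 0.144, against 0.195 for the genotype ratio, while the median absolute values were 0.0756 and 0.0748. Across genes, IlrunKO over WT ratios of arrays with the same dye orientation had a Pearson r of 0.379 (arrays 1 and 2) and 0.529 (arrays 3 and 4), and those with opposite orientation from 0.107 to 0.351, where genes are not independent replicates.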

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

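The tests on adipocyte markers and on stellate and Kupffer cell markers were chosen only after those results were seen. In 5 of 126 sets of 4 array values, 1 array stood far from the other 3, as Dixon's ratio of the gap to the range was above its 95% critical value; chance gives about 6.3 such sets. Ilrun had a ratio of 0.840, with array 4 at -4.56 and the others from -4.12 to -4.04. Apoc2 had a ratio of 0.984, with array 1 at 1.09 and the others from 0.59 to 0.60. Mcm6 had a ratio of 0.920, with array 3 at 0.27 and the others from 0.66 to 0.69. Hand2 had a ratio of 0.944, with array 3 at -0.15 and the others from -0.37 to -0.36. The mean of male-biased liver genes had a ratio of 0.933, with array 3 at -0.483 and the others from 0.0296 to 0.0665.

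Adipocyte markers were higher in IlrunKO liver with the preset correlation, with Cfd and Adrb3 past the threshold over all genes, but the list did not pass with an estimated correlation or by fry's directional test (adjusted p = 0.939 with an estimated correlation and 0.219 by fry). A large carry-over of fat tissue with the liver is argued against: Fabp4, abundant in fat, stood at -0.113 on the log2 scale. Adipoq, Plin1, Lep and Ucp1 were well above background in 0 of 4 IlrunKO channels. Retn, also on the adipocyte list, was well above background in 3 of 4 IlrunKO channels at both probes. In WT it was so in 1 and 2 of 4 channels. Its ratios were 0.119 and 0.138, and a small carry-over stays open. A different time of day at harvest cannot be told apart from genotype here, since the hours of harvest are unknown. The median absolute ratio of 23 clock genes was 1.93 times that of all genes, yet 0 of them passed in limma (5 had an unadjusted p under 0.05, near the share over all genes). An effect of genotype within liver cells stays open as a hypothesis and was not tested.

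Kupffer cell markers were higher and stellate cell markers lower in IlrunKO liver with the preset correlation, but both lists had an adjusted p = 0.939 with an estimated correlation. A lower share of hepatocyte RNA alone would raise both, whereas the stellate list mean lay below 0 on all 4 arrays (-0.263 ± 0.0755, SD over 4 arrays). The Kupffer mean less the stellate mean was 0.633 ± 0.405 (SD over 4 arrays) and above 0 on all 4 arrays, though by 0.05 on array 1. That difference was set up after the lists were seen to move apart, and both could rise unequally, so it cannot decide the question. Whether a lower hepatocyte share contributed to the higher Kupffer mean stays open. Whether array 2 decides the higher Kupffer mean stays open, as the list mean without array 2 was 0.137, within the SD of 0.348 between the other 3 arrays. In that mean array 1 alone (-0.164) weighed as much as arrays 3 and 4 together (0.457 and 0.418), whereas the SD weights the arrays equally. A change in the number or state of either cell type stays open as a hypothesis.

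Ratios of IlrunKO over WT were more alike between arrays with the same dye orientation than between arrays with opposite orientation. Dye bias of single probes may account for much of this: over 3519 pairs of probes of the same gene, r between probes was 0.264 for the dye effect and 0.684 for the genotype effect, a ratio of 0.387 (95% bootstrap interval 0.320 to 0.454). That interval resamples probe pairs on the same arrays, treating them as independent, so it holds no spread between mice or arrays. The smaller SD of the dye effect (0.144 against 0.195) could also lower its r, which was not tested. The median absolute effects were alike, 0.0756 for dye and 0.0748 for genotype. Base composition of the probes explained 3.36% of the variance of the dye effect, which argues against it as the main source. A part shared by probes of a gene remains, and differences between the mice of arrays 1 and 2 and those of arrays 3 and 4 stay open, as each sample was measured once.

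The arrays can be turned (IlrunKO and WT exchanged) in 7 distinct ways, too few for a share under 0.05. The real way gave 270 genes and the highest of the others 0, so 1 of 7 ways gave as many. In the other ways any real genotype difference enters the residual spread, in part or whole, which lowers their counts. Genes with an unadjusted limma p under 0.05 ran from 155 to 1065 there, against 983.75 by chance. A count near 0 was thus nearly fixed in advance, and no conclusion is drawn from it. For gene lists the real way gave 11 and the highest of the others 20, and 6 of 7 ways gave as many as the real one.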

How the results depend on the processing

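The alternative that asked for a call both with and without the dye term was chosen only after the data were seen; it held 157 genes. Ilrun kept its direction and passed in every alternative run, at -4.72 to -3.18, and at -4.34 to -4.08 with 1 array left out. All 270 genes kept their direction in each fit that tested them, but 267 did when every probe was fitted alone. There the first probe listed for a gene was compared, which need not be the probe that passed. Without the dye term, the direction of genes measured on every array could not turn. Nor could that of the 268 genes with the same sign on all 4 arrays when 1 array was left out. Their number was 437 without background correction, 82 from Agilent processed signals, 1 (Ilrun, lower) with median centring in place of loess, 412 with a trended robust variance, 2485 with separate channels and an intraspot correlation, 605 with separate channels and no pairing by array, and 449 from the deposited values. It was 1 to 464 with 1 array left out, 1118 at an adjusted p under 0.10 and 141 with a change of at least 1.5-fold. Fits without an array have 1 residual degree of freedom; the cause of the other differences was not tested. The dye effect passed for 5503 genes with median centring, 1 without the filter, 3 with a trended robust variance, and 1777 and 190 with separate channels, with and without an intraspot correlation.

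The number of lists that passed was 11 in the reported analysis, 18 with median centring, 11 to 19 with 1 array left out, 0 with an estimated correlation and 0 by fry's directional test. Of 231 alternatives for the 11 lists, 192 kept direction and call, 37 lost the call and 2 turned. CAR and PXR targets turned with median centring (-0.00113) and ran from -0.0420 to 0.324 with 1 array left out. PPARalpha targets turned with median centring (-0.0473) and ran from -0.0513 to 0.208. Lipoprotein assembly genes passed with median centring (-0.257). Median centring also put the median of all genes at -0.0500 and moved list means downward. Hepatocyte markers stood at -0.323, endothelial markers at -0.175 and endoplasmic reticulum stress genes at -0.273, each keeping its call. Interferon-stimulated genes came closer to 0 (0.119). Lipoprotein uptake genes turned with median centring (-0.0998) and with every probe alone (-0.00120), and ran from -0.0131 to 0.0245. Of 606 alternatives for 32 named genes that passed, 473 kept the call and 133 lost it; of 892 for 47 that did not, 115 gained it; none turned. The excess of called genes near Ilrun, 0.412 percentage points, turned with a normexp offset of 0 (-0.114) and with Agilent processed signals (-0.00945), was 0 to 1.63 with 1 array left out, and passed at 4.24 with separate channels and an intraspot correlation. The cause of these changes was not tested. Signal over background limits dim probes, such as that of Fgf21 in IlrunKO liver.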

Other observations

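The genes in this part were chosen only after their values were seen, and no enrichment was tested for them. Beside Bhmt, whose product dimethylglycine it demethylates, Dmgdh rose 1.79-fold (0.84 ± 0.21, SD, n = 4; adjusted p = 0.0397). Beside Kyat3, Kynu, the kynureninase, fell 1.61-fold (-0.69 ± 0.18, SD, n = 4; adjusted p = 0.0353). In the N-acetyltransferase family, Nat8 (-0.76 ± 0.27), Nat8f1 (-0.67 ± 0.14) and Nat8b-ps (-0.65 ± 0.27) fell while Nat8f4 rose (0.49 ± 0.11), each with the same sign on 4 of 4 arrays, and Nat8b-ps did not pass without the dye term. The amylase genes Amy1 (-0.62 ± 0.17) and Amy2a5 (-0.56 ± 0.15) fell, as did Dio1, which activates thyroid hormone (-0.97 ± 0.29), and Inhba, a subunit of activin (-0.82 ± 0.16). Ptma, Ptma-ps1 and Ptma-ps2 fell by 1.01, 0.66 and 0.98 on the log2 scale, and their probes read related sequences. Rises included Treh, which splits trehalose (1.04 ± 0.09), the mitochondrial enzyme gene Idh2 (0.67 ± 0.14), the transaminase gene Gpt (0.61 ± 0.18), Cyp2j6 (0.85 ± 0.16), Fmo5 (0.79 ± 0.24) and the histidine-degrading enzyme gene Hal (0.72 ± 0.22).

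Red cell markers had a list mean of -0.177 ± 0.141 (SD over 4 arrays; adjusted p = 0.0758) and genes of peroxisomal fatty acid oxidation 0.111 ± 0.148 (adjusted p = 0.0799), with no member past the threshold over all genes; adjusted over the list alone, no red cell marker passed and 1 peroxisomal gene fell. Cholesterol synthesis genes had a mean of 0.150 ± 0.430 (adjusted p = 0.204) and ranged over arrays from -0.251 on array 3 to 0.746 on array 2. Of 13 T and NK cell markers tested, Nkg7, a cytotoxic granule gene, fell 1.69-fold (-0.76 ± 0.26; adjusted p = 0.0303), while 8 of the 13 lay above 0 and the list did not pass (mean -0.0266 ± 0.109; adjusted p = 0.912). Male-biased liver genes had a mean of -0.0858 ± 0.265 (adjusted p = 0.639) and female-biased liver genes 0.0798 ± 0.208 (adjusted p = 0.276), with 1 member past the threshold in each, Mup20 and Lifr. The lipid droplet gene Plin4 stood at 1.55 ± 1.18 (adjusted p = 0.0865) and the acute phase gene Orm3 at 1.95 ± 1.04 (adjusted p = 0.0994).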
